A study of Xenopus laevis with 45 samples.

How the data were processed

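The study sequenced RNA of whole Xenopus laevis embryos kept in 0.1x MBS. Per the labels' protocols, 8-cell embryos were injected into 4 vegetal blastomeres with 10 ng ERFE MO1, 20 ng ERFE MO2, or 10 or 20 ng of a standard control morpholino, or were left uninjected. Embryos were collected at stages 35/36, 37/38 and 41. RNA was extracted with Trizol, and libraries were made with the TruSeq RNA v2 kit and run on lanes 1 to 5. The deposited values are read counts per gene, 1 file per library. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.17.1.14, reads were checked with FastQC 0.11.5, aligned with STAR 2.5.2a and counted with featureCounts 1.5.0-p1, and DESeq2 1.8.2 was used for differential expression. Those test results were not used here. The genome build, the annotation and the handling of reads that map to several genes are not given in the sources used here. The TruSeq RNA v2 kit does not mark strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart, and homeologous copies (names ending in .L and .S) can share reads, so a difference between such copies is uncertain.

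Each file holds 45038 gene identifiers; 28755 end in .L or .S, and 23450 carry a gene symbol, of which 18416 (78.5%) match a symbol of the RefSeq table supplied. Erythroferrone is listed as fam132b.L; the RefSeq table has an L copy and no S copy. Normalization factors are 0.936 to 1.07. Counting intervals and the floor of 3 counts, taken over a group for fold bounds and per library for CPM, cover counting error alone.

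All tests were computed here in R 4.3.3. Genes were kept by filterByExpr of edgeR 4.0.16 (count minimum 10, by group), leaving 31817 genes and 99.97% of counts. Counts were scaled by TMM and fitted with the edgeR quasi-likelihood model with 1 term per group over all 45 libraries (30 residual degrees of freedom, biological coefficient of variation 0.20). The comparisons are each ERFE morpholino against the same amount of control morpholino at each stage, each control morpholino against uninjected embryos, the difference between MO1 and MO2 responses at each stage, the difference between stage 41 and stage 35/36 responses of each morpholino, and stage 41 against stage 35/36 in uninjected embryos. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the genes of a comparison; a gene is called changed at an adjusted p under 0.05. Adjusted p-values of genes are from edgeR and those of lists from camera unless another tool is named. Standard errors are the absolute log2 fold change divided by the root of the F statistic, and fold changes use a prior count of 0.125. CPM values are counts scaled to the TMM-adjusted library size.

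A total of 22 gene lists was written before the data were examined: globins, erythroid and haem synthesis, leukocytes, endothelium, heart muscle, skeletal muscle, liver, exocrine pancreas, endocrine pancreas and gut, intestine stomach and lung, pronephros, BMP targets, iron handling, hypoxia and glycolysis, p53 targets, interferon and innate immune response, unfolded protein and amino acid stress, cell cycle, neurons, eye, epidermis and cement gland, and notochord cartilage and matrix. Lists of at least 5 genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 3) with the preset correlation of 0.01 and adjusted over the lists of a comparison; camera with a correlation estimated per list and fry were run beside it. Setting list genes with 0 counts throughout a group to their bound changed no median. The stage score of a library is the slope of its log2 CPM, relative to the uninjected stage 35/36 mean, on the uninjected log2 fold change over 5051 genes called between those stages with an absolute log2 fold change over 1; groups were compared by permutation within stages (8000 relabelings).

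Genes are named by rules also fixed before the data were examined: the targeted gene; up to 6 genes per direction called with both morpholinos; up to 4 per direction and ERFE comparison of the remaining called genes with the largest fold changes and a mean of at least 1 CPM in the higher group; up to 3 per direction in the other comparisons; and up to 4 per list with the smallest p-values, printed for lists with a call and for iron handling. A symbol takes 1 place in each of these. The comparisons, tests and alternatives were also fixed then, apart from the alternatives named as later in the sensitivity part.

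Alternatives were RLE scaling, no gene filter, DESeq2 1.42.0, a fit to the stages compared alone, a lane term, replicate number within stage as a block (24 residual degrees of freedom, coefficient of variation 0.11), and leaving out each library. The labels do not say what the replicate numbers share. The deviations of same-numbered libraries from their group means correlated above 0.1 in 38 of 39 pairs (median 0.487, maximum 0.718). Every library correlated best with its own number (39 of 39), also between uninjected stages 41 and 35/36. This hints at shared handling or lanes, so the pairing comes from the data. The exception was the library labelled ERFE MO2 stage 35/36 replicate 1 (0.0777; lowest of the other comparisons 0.309), so blocked values of comparisons that include its group are given in the sensitivity part alone. Deviations from a mean of 3 push the correlations with other numbers below 0.

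The tests were run on simulated data with the means and library sizes of the MO1 stage 41 comparison. With 200 changed genes edgeR found 0 of 67 at 1.5-fold, 36 of 67 at 2-fold and 66 of 66 at 4-fold with 0 false calls; the block found 47, 62 and 66 with 13 false calls among 188 (6.92%), and DESeq2 4, 42 and 66 with 0 false calls. The simulated counts held a shift shared by same-numbered libraries and a spread taken from the block fit, so they favour the block. They do not test whether the real libraries share such a shift. In these simulated data changes under 2-fold were often missed without the block. In the MO2 stage 41 comparison of the same simulated data, which held no changed genes, edgeR called 0. The block and DESeq2 were not tested on that comparison. Library pairs were compared by chi-square per gene over genes with at least 20 counts in the pair.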

Results

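Whole Xenopus laevis embryos were sequenced after knockdown of erythroferrone (ERFE), a hormone secreted by red blood cell precursors that binds bone morphogenetic proteins (BMPs). Antisense morpholinos were injected into 4 vegetal blastomeres of 8-cell embryos: 10 ng of ERFE MO1, 20 ng of ERFE MO2, or the same amounts of a standard control morpholino (cMO). Uninjected embryos were sequenced as well. Each of the 5 conditions was collected at stages 35/36, 37/38 and 41, with 3 libraries per group, giving 15 groups and 45 libraries. The libraries hold 19342567 to 41922031 assigned counts (median 32828061) and detect 34351 to 36061 genes, and no gene takes more than 0.868% of a library. A gene with 0 counts in a library can still have been present at up to 3 counts, which is 0.0716 to 0.155 depth-scaled counts (CPM). Log2 fold changes are given with the standard error (SE) of the fit, group means with the standard deviation, and every group has n = 3. Nothing in the labels says that the libraries of a group come from separate clutches, so the p-values measure only the spread between these samples, which may be technical.

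The targeted gene was present at low levels in every library. Only the L copy of erythroferrone, fam132b.L, is in the files, at 27 to 346 counts per library. In uninjected embryos it was measured at 3.18, 3.02 and 5.06 CPM (replicates 1, 2 and 3) at stage 35/36, 4.48, 4.67 and 5.32 CPM at stage 37/38, and 4.75, 9.16 and 8.23 CPM at stage 41. With 10 ng cMO the values were 1.88, 2.88 and 4.71 CPM, then 3.99, 5.16 and 5.90 CPM, then 4.24, 8.49 and 8.69 CPM at the same stages. ERFE MO1 libraries had 2.75, 2.30 and 4.76 CPM, then 2.86, 2.81 and 4.61 CPM, then 2.32, 5.41 and 7.03 CPM. The 20 ng cMO libraries had 2.44, 2.14 and 4.0 CPM, then 3.80, 3.98 and 6.42 CPM, then 4.37, 7.81 and 8.38 CPM. In ERFE MO2 libraries it was 2.93, 1.40 and 3.21 CPM, then 1.95, 2.41 and 3.90 CPM, then 2.24, 5.12 and 3.98 CPM.

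The targeted transcript was not called as changed by either morpholino in the edgeR quasi-likelihood (QL) test with Benjamini-Hochberg adjustment. For MO1 the log2 fold change of fam132b.L was 0.05 ± 0.41 at stage 35/36 (adjusted p = 1.0), -0.55 ± 0.40 at stage 37/38 (adjusted p = 0.94) and -0.54 ± 0.39 at stage 41 (adjusted p = 0.65). For MO2 it was -0.17 ± 0.41 (adjusted p = 1.0), -0.78 ± 0.40 (adjusted p = 1.0) and -0.86 ± 0.40 (adjusted p = 0.53). At stages 37/38 and 41 the gene was lower in 3 of 3 replicate numbers with each morpholino. With replicate number as a block it passed for MO1 at stage 41 (adjusted p = 0.021, range over the alternatives 0.0056 to 0.83) and for MO2 at stages 37/38 (0.017, range 0.0037 to 1.0) and 41 (0.0020, range 3.4e-04 to 0.95). Against uninjected embryos the 10 ng cMO differed by -0.25, 0.05 and -0.05 log2 units and the 20 ng cMO by -0.39, -0.03 and -0.11, all with adjusted p = 1.0. A morpholino that blocks translation need not lower its transcript, and whether MO1 and MO2 act on translation or on splicing is not given in the sources used here, so the degree of knockdown cannot be read from these values.

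**Figure D1:**
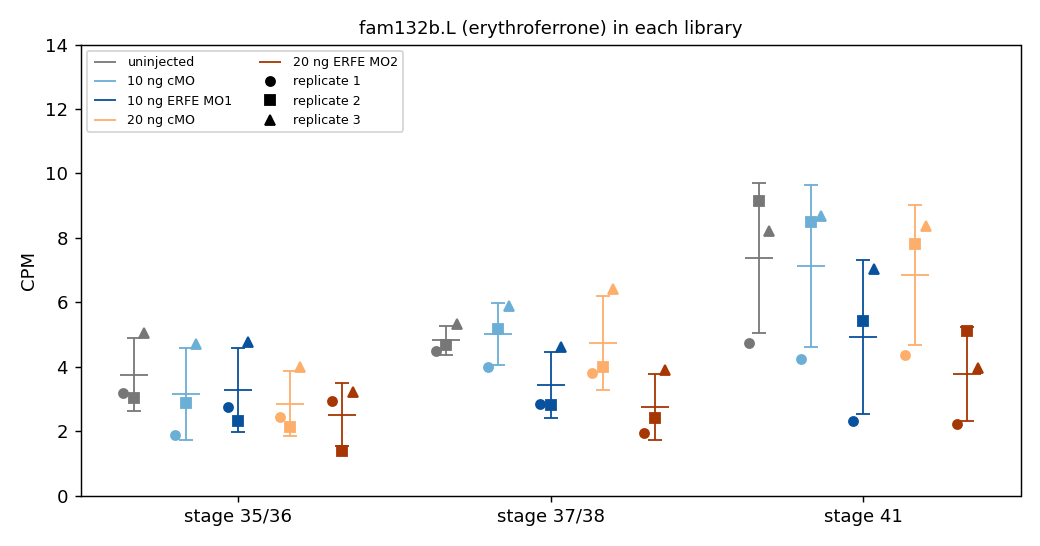
Expression of fam132b.L in CPM (vertical axis) in each of the 45 libraries, by stage and condition; points are libraries shaped by replicate number, and bars are group means with standard deviation. At stage 41 the mean is 7.14 CPM with 10 ng cMO and 4.92 CPM with MO1, and 6.85 CPM with 20 ng cMO and 3.78 CPM with MO2, while points of the groups overlap.

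Growth hormone releasing hormone transcripts were higher in embryos with control morpholino than in uninjected ones, a comparison that does not part the oligo from its injection. At stage 35/36 ghrh.S, which encodes the hypothalamic peptide that drives growth hormone release, had 0 counts in uninjected embryos and 1.46 ± 0.797 CPM with 10 ng cMO, at least 44.6-fold, or 1.93 ± 0.633 CPM with 20 ng, at least 59.1-fold (counting error only). Its other copy ghrh.L rose by 4.16 ± 0.52 log2 units at stage 37/38 and 4.34 ± 0.52 at stage 41 with 10 ng (adjusted p = 6.5e-05 and 3.4e-05), and by 4.58 ± 0.52 and 4.72 ± 0.52 with 20 ng (6.6e-06 and 4.4e-06). Then ghrh.S at stage 37/38 rose by 4.72 ± 0.66 with 10 ng (5.2e-04) and 5.22 ± 0.65 with 20 ng (5.4e-05). With 20 ng rpn2.S, a subunit of the enzyme that attaches N-glycans to proteins, was lower by 0.90 ± 0.15, 0.94 ± 0.15 and 0.83 ± 0.15 at the 3 stages (adjusted p = 0.0056, 0.0026 and 0.024). The mitochondrial pyrophosphatase gene ppa2.S fell by 0.46 ± 0.08 at stage 35/36 (0.0060). All held in 3 of 3 replicate numbers, which calling a gene favours, here and below.

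In total 2, 2 and 2 genes changed with 10 ng cMO at stages 35/36, 37/38 and 41, and 5, 4 and 4 with 20 ng. Beyond ghrh.L and ghrh.S at each stage and dose, these are rpn2.S, rpn2.L and at stage 35/36 ppa2.S, named in full after their values were seen; rpn2.L fell by 0.86 ± 0.15, 0.92 ± 0.15 and 0.81 ± 0.15 with 20 ng (adjusted p = 0.0060, 0.0026 and 0.024). With 10 ng the closest genes that did not pass were rpn2.S (-0.65, adjusted p = 0.78) and chmp7.L (0.51, 1.0) at stage 35/36, dlg2-like.1.S (-1.36, 0.51) and rpn2.L (-0.64, 0.61) at stage 37/38, and rpn2.L (-0.73, 0.16) and erlin2.L (0.47, 0.83) at stage 41. With 20 ng they were nap1l4.S (-0.50, 0.48) at stage 37/38 and erlin2.L (0.54, 0.15) at stage 41. Blocking on replicate number called 5, 4 and 15 genes with 10 ng and 22, 13 and 21 with 20 ng. Several of the near misses passed in that fit: rpn2.S (adjusted p = 0.031, range over the alternatives 0.016 to 1.0), rpn2.L (0.019 and 0.0026, ranges 0.0080 to 1.0 and 9.4e-04 to 1.0), erlin2.L (0.034 with 10 ng and 0.0061 with 20 ng, ranges 0.026 to 1.0 and 0.0060 to 1.0) and nap1l4.S (0.016, range 0.0093 to 1.0). At stage 41 the 10 ng count was 1 without replicate 1 of cMO or without any uninjected library. The 20 ng count was 2 at stage 35/36 without cMO replicate 1 or 3 or uninjected replicate 2, and 3 without uninjected replicate 3. It was 2 at stage 37/38 without cMO replicate 1 or 3, and 2 at stage 41 without those replicates or without any uninjected library.

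ERFE MO1 at stage 35/36 raised p53 target genes. The feedback regulator gene mdm2.L rose by 1.68 ± 0.22 log2 units (adjusted p = 3.5e-05) and sesn1.S, a sestrin gene induced by p53, by 1.59 ± 0.22 (6.2e-05). Large increases were seen in rpl3l.S, a ribosomal protein gene of striated muscle (4.84 ± 0.77, 4.6e-04), nppb.S, a cardiac natriuretic peptide (3.42 ± 0.72, 0.017), and lif.S, a cytokine (3.40 ± 0.68, 0.012). Lower were ctgfl.L (-1.79 ± 0.42, 0.042), the fibrinogen chain gene fgb.S (-1.54 ± 0.34, 0.027) and hes3.1.S, a repressor of the Hes family (-1.26 ± 0.28, 0.026). Each held in 3 of 3 replicate numbers. In total 124 of 31817 genes changed (112 higher, 12 lower, 16 without symbol). Blocking on replicate number gave 795 genes (447 higher, 348 lower), DESeq2 228, the lane term 296, and a fit to this stage alone 45. The count was 34 without MO1 replicate 1, and 65, 45 and 49 without cMO replicates 1, 2 and 3. Against uninjected embryos 122 of 124 kept their sign and 93 passed. Shared ERFE libraries build in part of this agreement, here and below.

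MO1 raised p53 target genes at stage 37/38 as well. Here mdm2.L rose by 1.83 ± 0.22 (adjusted p = 6.3e-06) and eda2r.L, a death receptor of the tumour necrosis factor family, by 3.78 ± 0.45 (6.3e-06). Other large increases were in rpl3l.S (5.29 ± 0.82, 2.6e-04), the chemokine gene ccl19.S (5.13 ± 1.24, 0.038), lif.S (4.53 ± 0.75, 8.0e-04) and rnf223.L (4.08 ± 0.99, 0.042). The steroid 21-hydroxylase gene cyp21a2.1.L fell by 3.17 ± 0.61 (0.0052), the liver tryptophan dioxygenase gene tdo2.L by 2.67 ± 0.64 (0.038), and the muscle repressor gene msc.S by 1.99 ± 0.37 (0.0029). All were so in 3 of 3 replicate numbers, and 191 genes changed in total (160 higher, 31 lower, 33 without symbol). A block for replicate number gave 1158 genes (608 higher, 550 lower), the lane term 417, a fit to this stage alone 301 and DESeq2 350. Leaving out MO1 replicate 1 gave 61 genes, MO1 replicate 3 gave 122, and cMO replicates 1, 2 and 3 gave 83, 84 and 89. Against uninjected embryos 189 of 191 kept their sign and 155 passed.

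MO1 changed 479 genes at stage 41, 309 higher and 170 lower. The p53 target gene eda2r.L (3.07 ± 0.43, adjusted p = 1.0e-04) was still higher, together with rpl3l.S (4.64 ± 0.79, 0.0011), lif.S (4.09 ± 0.75, 0.0024) and the cyclin kinase inhibitor gene cdkn2b.S (3.58 ± 0.86, 0.023). The regenerating family gene reg4.S fell by 3.37 ± 0.77 (0.016). Each held in 3 of 3 replicate numbers. Of the 479 genes 90 carry no symbol. The count was 4256 (1728 higher, 2528 lower) with replicate number as a block, 756 with DESeq2, 1566 with the lane term and 113 in a fit to this stage alone. Without cMO replicate 3 it was 108 and without MO1 replicate 2 it was 217. Against uninjected embryos 476 of 479 kept their sign and 353 passed.

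ERFE MO2 changed few genes at stage 35/36. The cell cycle phosphatase gene cdc25b.S fell by 0.59 ± 0.11 log2 units (adjusted p = 0.049) and caprin2.S by 0.96 ± 0.18 (0.034). Replicate number 1 does not pair here. Of the remaining 4 genes, named after their values were seen, ghrh.L fell by 3.83 ± 0.48 (7.8e-05), ghrh.S fell by 3.45 ± 0.56 (0.0070) and rpn2.S rose by 0.76 ± 0.15 (0.049), while wdr38.S had 60 counts against 2 (ratio 32.3, 95% counting interval 8.57 to 273, adjusted p = 0.0070). The total was 6 genes, 2 higher and 4 lower, with 1701 at unadjusted p under 0.05; DESeq2 called 45, a fit to this stage alone 2 and the lane term 23. Against uninjected embryos 3 of 6 kept their sign and 0 genes passed.

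The library labelled ERFE MO2 stage 35/36 replicate 1 matches an MO1 library of stage 37/38 more closely than its own group. Its chi-square per gene against MO1 stage 37/38 replicate 2 is 1.22 over 29841 genes, against 3.93 for the next closest of 990 pairs and 10.8 for the closest pair within a group. Without the library labelled ERFE MO2 stage 35/36 replicate 1, 20 genes changed at stage 35/36. These include ghrh.L, caprin2.S and wdr38.S of the 6 genes, but not cdc25b.S, ghrh.S and rpn2.S. Among them the plasma protein genes plg.S (-2.01 ± 0.33, adjusted p = 0.0061), serpina1.S (-1.83 ± 0.34, 0.029), ttr.L (-1.97 ± 0.38, 0.034) and gc.S (-1.84 ± 0.38, 0.047), all products of liver, were lower; these were chosen after their values were seen. The count was 1 without MO2 replicate 2, MO2 replicate 3 or cMO replicate 1, and 3 without cMO replicate 3.

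MO2 changed 31 genes at stage 37/38, 16 higher and 15 lower. The fibrinogen gene fgg.L fell by 1.70 ± 0.36 (adjusted p = 0.041), caprin2.S by 1.07 ± 0.18 (0.0039) and the cytochrome P450 gene cyp2c18.S by 0.80 ± 0.12 (0.0025). Higher were thap1.S (0.96 ± 0.18, 0.019), phf12.S (0.87 ± 0.14, 0.0028), the polyamine synthesis gene odc1.S (0.80 ± 0.13, 0.0039) and the glycolysis gene pgam1.L (0.70 ± 0.12, 0.0039). These held in 3 of 3 replicate numbers, and 7 of the 31 genes carry no symbol. Replicate number as a block raised the count to 514 (199 higher, 315 lower), the lane term to 94, a fit to this stage alone to 54 and DESeq2 to 79. The count was 6, 12 and 11 without cMO replicates 1, 2 and 3, and 6 and 7 without MO2 replicates 1 and 2. Against uninjected embryos 28 of 31 kept their sign and 13 passed.

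MO2 changed 131 genes at stage 41, 76 higher and 55 lower. The leukocyte adaptor gene fyb.L rose by 1.83 ± 0.35 (adjusted p = 0.010) and the potassium channel subunit gene kcne3.S by 1.65 ± 0.35 (0.022), while zan.L fell by 4.41 ± 0.97 (0.028), each in 3 of 3 replicate numbers. Of the 131 genes 26 carry no symbol. Replicate blocking called 1846 (783 higher, 1063 lower), DESeq2 309, the lane term 700 and a fit to this stage alone 25. Without the library labelled ERFE MO2 stage 35/36 replicate 1, which is not in this comparison but enters the shared variance, the count was 192. It was 13 without MO2 replicate 2, 52 without MO2 replicate 1, and 200, 31 and 18 without cMO replicates 1, 2 and 3. Against uninjected embryos 129 of 131 kept their sign and 91 passed.

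Genes that changed in the same direction with both ERFE morpholinos at stage 41 include sterol synthesis and stomach genes. Squalene epoxidase, sqle.L, rose by 2.0 ± 0.37 with MO1 and 1.87 ± 0.38 with MO2 (adjusted p = 0.0029 and 0.015), and hmgcs1.L, an early enzyme of the same pathway, by 1.34 ± 0.23 and 1.24 ± 0.23 (0.0014 and 0.010). Also higher were g6pc.L, which releases glucose in liver (1.84 ± 0.47 and 2.35 ± 0.47, 0.036 and 0.015), stc2.L (1.19 ± 0.21 and 1.16 ± 0.21, 0.0014 and 0.0061), nov.L (1.25 ± 0.24 and 1.15 ± 0.24, 0.0040 and 0.022) and the endothelial lipase gene lipg.S (1.54 ± 0.18 and 1.05 ± 0.18, 1.1e-05 and 0.0045). The gastric proton pump gene atp4a.L fell by 3.46 ± 0.76 and 3.80 ± 0.78 (0.011 and 0.018), and the mucin gene muc5ac.L fell by 3.19 ± 0.60 and 2.62 ± 0.59 (0.0031 and 0.035). The sterol transporter gene abcg8.S fell by 3.75 ± 0.82 and 3.48 ± 0.78 (0.012 and 0.035), and the chemokine gene ccl5.L by 2.57 ± 0.65 and 3.26 ± 0.67 (0.035 and 0.018). The albumin-related gene alb-like.1.S had 3 counts with MO1 against 95 with cMO (29.6-fold lower, 95% counting interval 9.82 to 146) and fell by 3.68 ± 0.84 with MO2 (0.038). Also on this list is ghrh.L, which fell by 3.46 ± 0.48 and 3.31 ± 0.46 (6.9e-05 and 6.4e-04). All were so in 3 of 3 replicate numbers.

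Together 52 genes changed the same way with both morpholinos at stage 41 (34 higher, 18 lower), where 1.03 would be expected of independent lists, and 0 went opposite ways; the MO1 and MO2 comparisons use separate control libraries. At stage 37/38 there were 4 such genes against 0.0951 expected: ghrh.L (-3.70 ± 0.48 with MO1, adjusted p = 2.2e-05; -3.82 ± 0.47 with MO2, 4.3e-05), ghrh.S (-4.59 ± 0.62, 5.4e-05; -2.57, 0.025), rpn2.S (0.68 ± 0.15, 0.014; 0.73 ± 0.15, 0.034) and chmp7.L, a membrane remodelling protein gene (-0.61 ± 0.15, 0.037; -0.70 ± 0.14, 0.040). At stage 35/36 there were 2 against 0.00855 expected: ghrh.L (-3.76 ± 0.50 with MO1, 5.0e-05) and ghrh.S (-3.73 ± 0.59 with MO1, 5.2e-04), with the MO2 values given above. Since ghrh.L, ghrh.S and, with 20 ng, rpn2.S differ between control morpholino and uninjected embryos in the opposite direction, these overlaps need not reflect ERFE. Of the MO1-changed genes 96.0%, 76.4% and 94.2% had the same sign with MO2 at the 3 stages, against 60.6%, 58.9% and 64.0% of all genes. The first share rests in part on the library labelled ERFE MO2 stage 35/36 replicate 1, which is closest to an MO1 library; without it 78.2% of the same 124 genes had the same sign, against 56.1% of all genes. Replicate blocking gave 87 genes at stage 37/38 (9.25 expected, 1 opposite) and 821 at stage 41 (127 expected, 6 opposite), and DESeq2 gave 13, 8 and 125. The stage 41 count was 4 without MO2 replicate 2, 27 without MO2 replicate 1, 6 and 16 without 20 ng cMO replicates 3 and 2, and 21 without 10 ng cMO replicate 3. The stage 37/38 count was 1 without MO2 replicate 1 or 2 or 20 ng cMO replicate 1 or 3, and 2 without MO1 replicate 1 or 3, MO2 replicate 3 or 10 ng cMO replicate 1 or 3. The stage 35/36 count was 1 without any MO2 library or without 20 ng cMO replicate 1.

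**Figure D2:**
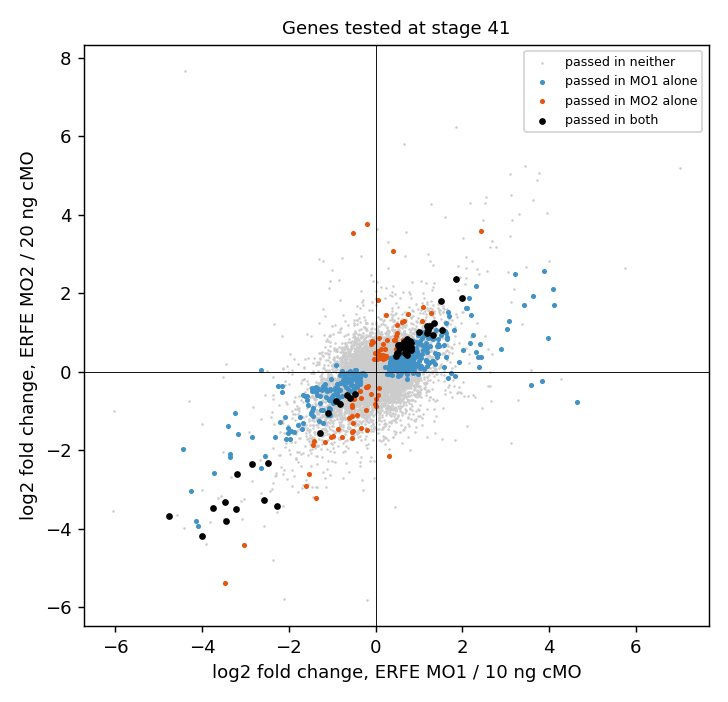
Log2 fold change of each tested gene at stage 41 with MO1 against 10 ng cMO (horizontal axis) and with MO2 against 20 ng cMO (vertical axis), coloured by where the gene passed. The 52 genes that passed in both lie in the lower left and upper right, and the Pearson correlation across all genes is 0.514.

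The p53 list was the clearest gene group with MO1, which need not reflect ERFE loss. Its 50 genes had median log2 fold changes of 0.34, 0.56 and 0.46 at stages 35/36, 37/38 and 41 (adjusted p = 1.5e-25, 1.6e-32 and 3.4e-14), calls that hold with an estimated correlation (3.7e-06, 3.5e-07 and 4.8e-04). Of the list 15, 18 and 12 genes rose and 0 fell; adjusted over the list alone 25, 26 and 23 rose and 1 fell at each stage. Beyond those above, sesn1.S rose by 1.35 ± 0.21 at stage 37/38 (adjusted p = 4.1e-04) and sesn2.L by 0.82 ± 0.14 at stage 41 (0.0015). With MO2 the medians were 0.28, 0.11 and 0.11 (adjusted p = 1.9e-08, 0.010 and 5.1e-04; 0.0083, 0.31 and 0.13 with an estimated correlation), and 0, 0 and 1 genes passed, btg2.S, an antiproliferative p53 target, at stage 41 (0.82 ± 0.20, 0.047); adjusted over the list alone there were 2, 0 and 3. Without the library labelled MO2 replicate 1 the MO2 median at stage 35/36 was 0.14 (adjusted p = 0.0033, and 0.28 with an estimated correlation).

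Cell cycle genes were lower with MO1. The 85 genes had medians of -0.11, -0.11 and -0.23 with MO1 (adjusted p = 0.0020, 2.9e-04 and 4.5e-12; adjusted p = 0.61, 0.49 and 0.048 with an estimated correlation). At stage 41, 76 of 85 were below 0, 3 fell over all genes, and adjusted over the list alone 17 fell and 1 rose. The 3 were mcm5.S, part of the replicative helicase (-0.58 ± 0.14, adjusted p = 0.021), e2f1.S, a transcription factor of S phase entry (-0.57 ± 0.14, 0.023), and cdc25b.S (-0.43 ± 0.11, 0.042). With MO2 the list was called at stage 37/38 in the other direction (median 0.06, adjusted p = 0.0019; adjusted p = 0.44 with an estimated correlation) with 0 genes passing and 1 over the list alone, and not at stages 35/36 and 41, although the replication licensing gene cdc6.L rose at stage 41 (0.70 ± 0.14, 0.014).

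Endothelial genes were lower with both morpholinos, at stage 35/36 from controls that were themselves raised in the median. The 65 genes had medians of -0.26, -0.33 and -0.33 with MO1 (adjusted p = 2.7e-10, 2.4e-15 and 1.1e-08; 0.045, 0.0067 and 0.048 with an estimated correlation) and -0.29, -0.32 and -0.20 with MO2 (1.3e-16, 5.5e-23 and 1.2e-06; 0.0078, 0.0011 and 0.13 with an estimated correlation). With MO1 at stage 41 the fenestral diaphragm gene plvap.L fell by 1.28 ± 0.21 (adjusted p = 6.9e-04) and the angiopoietin receptor gene tek.S by 0.89 ± 0.18 (0.0056), while the tip cell gene esm1 rose (esm1.S 2.24 ± 0.28, 2.0e-05; esm1.L 1.31 ± 0.29, 0.012). At stage 37/38 the adrenomedullin receptor subunit gene ramp2.L fell by 0.96 ± 0.22 (0.029) and esm1.S rose by 1.16 ± 0.28 (0.039). With MO2 at stage 41 gpr182.S fell by 0.85 ± 0.17 (0.013) and the endothelial receptor gene tie1.S by 0.66 ± 0.16 (0.045). Over all genes 0, 1 and 7 endothelial genes fell with MO1 and 0, 1 and 3 rose; 0, 0 and 2 fell with MO2. Adjusted over the list alone 1, 18 and 14 fell with MO1 and 4, 13 and 7 with MO2. Without MO2 replicate 1 the MO2 value at stage 35/36 was -0.24 (adjusted p = 1.8e-11, and 0.061 with an estimated correlation).

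Blood lists were lower in the median without any gene passing in most comparisons. The 44 erythroid and haem synthesis genes had medians of -0.06, -0.20 and -0.18 with MO1 (adjusted p = 0.30, 2.8e-04 and 0.0012; 0.53 and 0.42 with an estimated correlation for the called ones) and -0.13, -0.28 and -0.32 with MO2 (0.12, 9.6e-07 and 1.2e-06; 0.31 and 0.22 with an estimated correlation), with 0 genes passing over all genes or over the list alone. The 9 globins had medians of -0.26, -0.40 and -0.25 with MO1 and -0.15, -0.39 and -0.44 with MO2 and were not called (adjusted p from 0.071 to 0.81). With replicate number as a block they were called with MO2 at stages 37/38 (0.032, range over the alternatives 0.032 to 0.60) and 41 (0.022, range 0.022 to 0.56). The 39 leukocyte genes were called with MO1 at stage 41 (median -0.22, adjusted p = 0.0068; adjusted p = 0.46 with an estimated correlation), where laptm5.S, a lysosomal protein gene of blood cells, fell by 1.37 (0.042). They were called with MO2 at stages 37/38 and 41 (medians -0.39 and -0.19, adjusted p = 8.0e-08 and 0.0083; adjusted p = 0.31 and 0.56 with an estimated correlation) with 0 genes passing. At stage 37/38 this list was higher by 0.36 with 20 ng cMO than in uninjected embryos (adjusted p = 2.1e-08; adjusted p = 0.37 with an estimated correlation), so the fall with MO2 is measured from a raised control. With MO1 at stage 37/38 the leukocyte median was -0.19 but the mean 0.02 and the list was not called (0.15), except with the block (0.037, range over the alternatives 0.037 to 0.81).

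BMP target genes were higher at stage 41. The controls with MO2 then and with MO1 at stage 35/36 were themselves lower in the median than uninjected embryos. The 43 genes had a median of 0.27 with MO1 (adjusted p = 2.3e-08; 0.048 with an estimated correlation), 37 of 43 were above 0, 3 rose over all genes and 6 over the list alone. The 3 were id3.S, induced directly by BMP signals (0.38 ± 0.09, adjusted p = 0.026), and the homeobox genes msx1.S (0.56 ± 0.15, 0.042) and msx1.L (0.58 ± 0.15, 0.045). With MO2 the median was 0.17 (5.1e-04; adjusted p = 0.22 with an estimated correlation), 34 of 43 were above 0 and 0 passed over all genes or the list alone. Earlier the list was called only with MO1 at stage 35/36 (median 0.11, 0.0025; adjusted p = 0.56 with an estimated correlation, 0 genes passing); the medians were 0.06 with MO1 at stage 37/38 (0.22) and -0.02 and 0.02 with MO2 (0.49 and 0.91). The 39 iron handling genes were not called in any comparison (adjusted p from 0.23 to 0.98), although aco1.L, which encodes an iron responsive RNA binding protein, fell with MO1 at stage 41 (-0.37 ± 0.07, 0.0055).

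**Figure D3:**
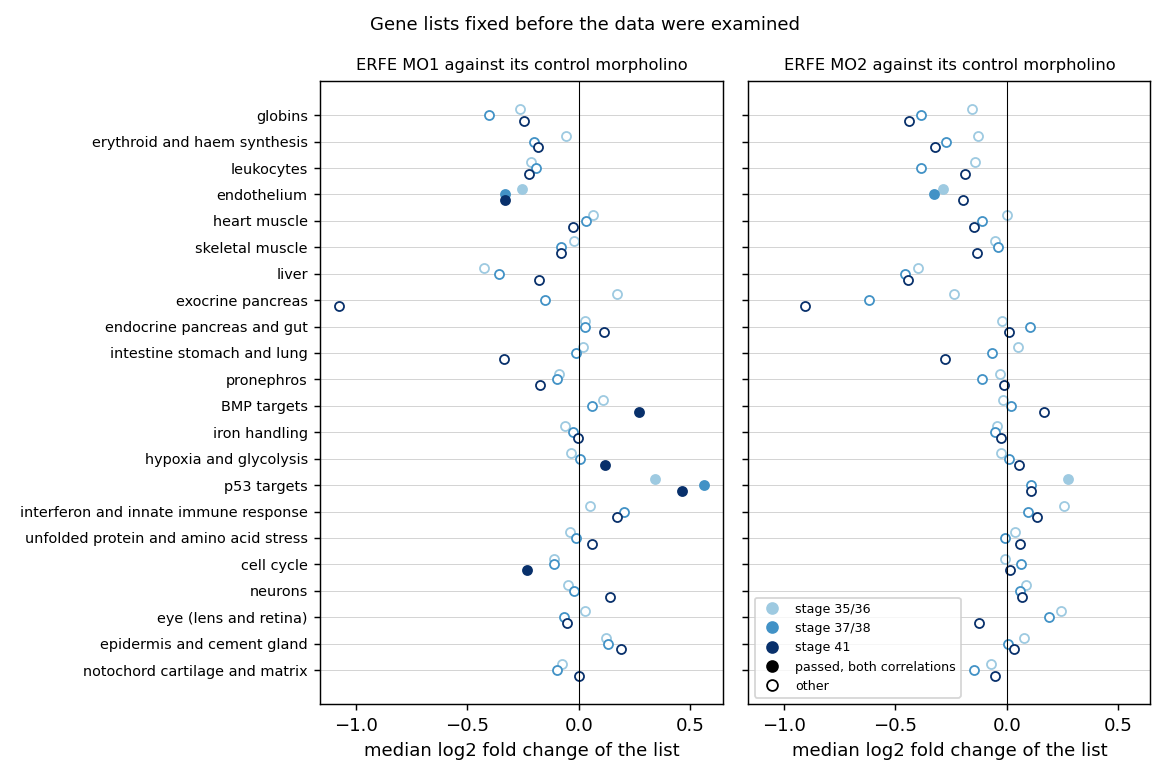
Median log2 fold change (horizontal axis) of each of the 22 gene lists with MO1 and with MO2 against their control morpholinos; points are stages, filled where the list passed with both the preset and an estimated correlation. The p53 list stands at 0.34 to 0.56 with MO1 and the endothelial list at -0.20 to -0.33 with both morpholinos.

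The liver list fell in the median, with few single genes passing. The 63 liver genes had medians of -0.43, -0.36 and -0.18 with MO1 (adjusted p = 1.5e-09, 4.0e-06 and 0.0029; adjusted p = 0.46, 0.49 and 0.46 with an estimated correlation) and -0.40, -0.46 and -0.44 with MO2 (1.2e-12, 2.1e-16 and 1.0e-10; adjusted p = 0.21, 0.11 and 0.19 with an estimated correlation). The MO2 median at stage 35/36 was -0.58 without MO2 replicate 1, called with the preset but not with an estimated correlation. With MO1 fgb.S fell at all 3 stages (-1.69 ± 0.34 at stage 37/38, -1.44 ± 0.34 at stage 41; adjusted p = 0.0086 and 0.021), and at stage 41 the phenylalanine hydroxylase gene pah.L (-1.01 ± 0.20, 0.0058), itih2.L (-1.48 ± 0.32, 0.011), itih2.S (-1.10 ± 0.25, 0.016) and fga.S (-1.29 ± 0.32, 0.031, named after its value was seen) fell too. With MO2 at stage 41 the protease inhibitor genes serpina1.S (-1.51 ± 0.32, 0.020) and serpina1.L (-1.32 ± 0.30, 0.036), the plasminogen gene plg.S (-1.53 ± 0.35, 0.039) and itih2.S (-1.06 ± 0.25, 0.045) fell. Counts over all genes were 1, 1 and 5 lower with MO1 and 0, 1 and 4 with MO2; adjusted over the list alone 3, 4 and 6 and 11, 7 and 18.

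Pancreas and stomach lists were called mainly at stage 41. The 18 exocrine pancreas genes had a median of -1.08 with MO1 (adjusted p = 4.5e-04; adjusted p = 0.25 with an estimated correlation), where the digestive enzyme gene cpa1.L fell by 3.72 ± 0.78 (0.0079) and the chaperone genes pdia2.S and pdia2.L by 1.71 ± 0.39 and 2.64 ± 0.60 (0.015 and 0.017). Over the list alone 5 fell and 1 rose. With MO2 the median was -0.91 (1.2e-06; adjusted p = 0.13 with an estimated correlation), with 0 genes passing and 9 lower over the list alone. The 59 genes of intestine, stomach and lung had medians of -0.34 with MO1 and -0.28 with MO2 (6.1e-05 and 4.3e-06; adjusted p = 0.31 and 0.22 with an estimated correlation). Of these atp4a.S fell along with atp4a.L (-3.22 ± 0.76 with MO1, 0.022; -3.49 ± 0.78 with MO2, 0.032), and with MO1 the brush border genes anpep.L (-1.08 ± 0.28, 0.036) and myo1a.S (-0.88 ± 0.23, 0.044) fell. Over all genes 4 and 2 fell, over the list alone 7 and 10. With MO1 at stage 37/38 the exocrine list was not called (median -0.15), although the chymotrypsin gene ctrb2.L had 36 counts against 0, at least 11.5-fold (0.019); with this gene at its bound the median is unchanged.

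Heart and muscle lists were called weakly. The 42 heart genes were called with MO2 at stages 37/38 and 41 (medians -0.11 and -0.15, adjusted p = 2.2e-05 and 0.0016; adjusted p = 0.11 and 0.22 with an estimated correlation), where the cardiac troponin gene tnni3.S fell at stage 41 (-0.83 ± 0.20, 0.045); over the list alone 3 and 4 fell. They were not called with MO1, although nppb.S rose at stages 37/38 (3.29 ± 0.69, adjusted p = 0.012) and 41 (3.03 ± 0.67, 0.012), and the atrial myosin genes myh6.L (-1.27 ± 0.30, 0.021) and myh6.S (-1.57 ± 0.37, 0.023) fell at stage 41 with mef2c.L (-0.37 ± 0.10, 0.047). The 52 skeletal muscle genes were called at stage 41 with MO1 (median -0.08, 0.013; adjusted p = 0.41 with an estimated correlation) and MO2 (-0.13, 0.0083; adjusted p = 0.34 with an estimated correlation). With MO1 the sarcomere genes actn2.S (-0.84 ± 0.20, 0.027) and mybpc1.S (-2.15 ± 0.56, 0.041) fell; 3 fell over the list alone, and with MO2 0 passed. At stage 37/38 the muscle regulator gene myog.L fell with MO1 (-0.77 ± 0.19, 0.048), where the list had a median of -0.08 and was called only with the block (0.15 without, 0.027 with it, range over the alternatives 0.027 to 0.71).

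Stress and immune lists were higher in places. The 62 hypoxia and glycolysis genes were called at stage 41 with MO1 (median 0.12, adjusted p = 0.0021; 0.033 with an estimated correlation), where ddit4.L, an inhibitor of growth signalling (0.69 ± 0.14, 0.0058), igfbp1.S (1.03 ± 0.24, 0.017), the adrenomedullin gene adm.L (1.11 ± 0.27, 0.023) and the glycolytic gene aldoa.L (0.50 ± 0.13, 0.035) rose. With MO2 the stage 41 median was 0.05 (0.018; adjusted p = 0.13 with an estimated correlation), and adm.S (1.51 ± 0.34, 0.038) and pgam1.L (0.48 ± 0.12, 0.050) rose. Over the list alone 9 rose and 2 fell with MO1 and 4 rose with MO2. The 56 genes of the unfolded protein and amino acid response had a median of 0.06 with each morpholino at stage 41 (0.011 and 0.019; adjusted p = 0.41 and 0.41 with an estimated correlation), with the amino acid transporter genes slc7a5.L (0.66 ± 0.12, 0.0026) and slc3a2.L (0.45 ± 0.11, 0.021) and the stress factor gene atf3.S (1.26 ± 0.33, 0.043) higher with MO1. The 61 interferon and innate immune genes were called with MO1 at stages 37/38 and 41 (medians 0.20 and 0.17, 1.3e-05 and 0.021) and with MO2 at all 3 stages (0.26, 0.09 and 0.13, 3.3e-07, 0.037 and 0.0082). With an estimated correlation these had adjusted p = 0.35 and 0.46, and adjusted p = 0.21, 0.59 and 0.46, and with the block the MO2 call at stage 37/38 was lost (0.12, range over the alternatives 0.12 to 0.60). At stage 35/36 the MO2 median was 0.12 and not called without MO2 replicate 1. The cytokine feedback gene socs3.L rose with MO1 at stage 37/38 (2.62 ± 0.64, 0.045).

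The remaining lists were called with the preset correlation alone. The 65 epidermis and cement gland genes had medians of 0.12, 0.13 and 0.19 with MO1 (adjusted p = 0.0048, 1.4e-04 and 7.8e-05; adjusted p = 0.56, 0.35 and 0.17 with an estimated correlation). The simple epithelial keratin genes krt8.S (0.60 ± 0.14, 0.029) and krt18.L (0.67 ± 0.16, 0.042) rose at stage 37/38, and krt18.L (0.87 ± 0.16, 0.0031), krt8.L (0.52 ± 0.12, 0.023) and the ionocyte factor gene foxi2.S (1.42 ± 0.35, 0.030) at stage 41; over the list alone 1, 4 and 6 rose. The 65 neuron genes were called with MO1 at stage 41 (median 0.14, 6.1e-04) and with MO2 at all 3 stages (0.09, 0.06 and 0.07; 0.013, 0.0096 and 0.018), with adjusted p = 0.41, 0.93, 0.59 and 0.58 with an estimated correlation; the motor neuron factor gene isl2.S (0.50 ± 0.12, 0.028) and the neurofilament gene nefl.L (0.54 ± 0.14, 0.045) rose with MO1. Neuron genes were lower with 20 ng cMO than in uninjected embryos with the preset correlation (-0.06, -0.09 and -0.06; adjusted p = 0.85, 0.42 and 0.53 with an estimated correlation), so the MO2 values are measured from a control that was itself lower in the median. The MO2 median at stage 35/36 was -0.06 and not called without MO2 replicate 1. With MO2 at stage 37/38 the 74 eye genes (median 0.19, 9.5e-04) and the 44 genes of endocrine pancreas and gut (0.10, 0.014) were higher, and the 62 notochord, cartilage and matrix genes lower (-0.15, 8.3e-04), with adjusted p = 0.59, 0.31 and 0.31 with an estimated correlation and 0 genes passing. The matrix list was also called with MO1 at stage 37/38 (-0.10, 0.027; adjusted p = 0.64 with an estimated correlation, 0.056 with the block, range 0.056 to 0.64), although its link protein gene hapln3.S rose (0.71 ± 0.17, 0.030). The 43 pronephros genes were called at stage 37/38 with MO1 (-0.10, 0.027) and MO2 (-0.11, 0.031), adjusted p = 0.35 and 0.31 with an estimated correlation; at stage 41 with MO1 the slit diaphragm gene nphs1.S rose (0.89 ± 0.17, 0.0042) and rgn.L fell (-1.04 ± 0.28, 0.047). In the 6 ERFE comparisons 6, 9 and 15 of 22 lists were called with MO1 and 5, 13 and 14 with MO2, of which 2, 2 and 5 and 2, 1 and 0 hold with an estimated correlation. The MO1 count at stage 41 was 7 without MO1 replicate 1, and the MO2 count at stage 35/36 was 8 without MO2 replicate 3 or cMO replicate 1 or 3. Leaving out MO2 replicate 1, the library closest to an MO1 library, gave calls at stage 35/36 for leukocytes (-0.34), pronephros (-0.07), cell cycle (0.08) and eye (-0.39), with the preset correlation alone.

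Some lists differed between control morpholino and uninjected embryos, without a gene passing. Leukocyte genes were higher with 10 ng at stages 35/36 and 37/38 (medians 0.24 and 0.32, adjusted p = 2.9e-04 and 2.2e-06) and with 20 ng (0.26 and 0.36, 7.0e-05 and 2.1e-08), and epidermis genes were higher with 20 ng at all 3 stages (0.08, 0.14 and 0.15) and with 10 ng at stage 37/38 (0.16). Heart genes were lower in 5 comparisons (medians -0.07 to -0.13) and so were skeletal muscle genes (-0.06 to -0.14), exocrine pancreas genes at stage 41 (-0.32 with 10 ng, -0.35 with 20 ng) and neuron genes with 20 ng (-0.06, -0.09 and -0.06). With 10 ng at stage 35/36 the erythroid list (-0.14), BMP targets (-0.06) and neurons (-0.01) were lower and endothelium (0.07) and interferon genes (0.09) higher; at stage 37/38 eye (0.17) and interferon genes (0.09) were higher. With 20 ng endothelium was higher at stage 35/36 (0.08), and at stage 41 the gut list (-0.08), the matrix list (-0.10) and BMP targets (-0.07, mean 0.02) were lower. None of these calls, 6, 6 and 3 lists with 10 ng and 6, 5 and 8 with 20 ng, held with an estimated correlation (adjusted p 0.17 or more). With the block the 10 ng calls for neurons (0.11, range over the alternatives 0.11 to 0.94) and for interferon genes at stage 37/38 (0.084, range 0.084 to 0.98) were lost. The block called 6 other cMO results: with 10 ng at stage 41 erythroid and epidermis genes (0.038 each, range to 0.99), with 20 ng globins (0.040, range to 0.97) and erythroid genes (0.033, range to 0.97) at stage 35/36, cell cycle genes at stage 37/38 (0.015, range to 0.96) and leukocytes at stage 41 (0.043, range to 0.78).

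The response to MO1 exceeded that to MO2 for p53 genes. At stage 37/38 the difference of log2 fold changes (MO1 minus MO2) was 2.98 ± 0.58 for eda2r.L (adjusted p = 0.032), 1.8 ± 0.30 for mdm2.L (0.017) and 2.0 ± 0.39 for fam189a2.S (0.032), in 3 of 3 replicate numbers, and -0.99 ± 0.20 for the chromatin factor gene phf12.S (0.032, lower in 2 of 3). In all 13 genes differed (11 higher with MO1, 2 lower), 141 with the block and 29 with DESeq2. The count was 0 without MO1 replicate 1 or 3, MO2 replicate 1, any 10 ng cMO library or 20 ng cMO replicate 3, 1 without MO2 replicate 2, 5 without 20 ng cMO replicate 1 and 38 without MO1 replicate 2. At stage 35/36 edgeR called 0 genes (746 at unadjusted p under 0.05, DESeq2 0, and 3 without the library labelled ERFE MO2 stage 35/36 replicate 1); among the smallest p were those of tinf2.L (0.92) and ttll12.L (0.95), each with adjusted p = 1.0. At stage 41 it called 0 genes (1046 at unadjusted p under 0.05, DESeq2 1, block 92, and 1 without MO2 replicate 3), the closest being eif4g3.S (-0.86, 0.16; 0.026 with the block, range over the alternatives 0.0040 to 0.70), myh1-1-2.L (-2.68, 0.49; 0.029, range 0.011 to 1.0) and rpl3l.S (5.4, 0.49; 0.038, range 0.0023 to 1.0). The median difference of the p53 list was 0.13, 0.44 and 0.21 at the 3 stages (adjusted p = 1.3e-07, 7.8e-19 and 1.4e-06; 0.021, 5.5e-05 and 0.038 with an estimated correlation), and that of the cell cycle list -0.29 at stage 41 (4.7e-16; 0.038 with an estimated correlation). The p53 difference at stage 35/36 was 0.40 without the library labelled ERFE MO2 stage 35/36 replicate 1, and was called with the preset and with an estimated correlation.

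Other lists differed between MO1 and MO2 only with the preset correlation (adjusted p 0.24 or more with an estimated one). At stage 35/36 these were BMP targets (0.15, adjusted p = 4.8e-04), interferon genes (-0.26, 9.6e-05), cell cycle (-0.09, 0.0018) and neurons (-0.14, 0.0011). Of these 4 only cell cycle (-0.16) was called without the library labelled ERFE MO2 stage 35/36 replicate 1; BMP targets (0.10), interferon genes (-0.10) and neurons (0.04) were not, and heart (0.15), liver (0.29) and eye (0.44) were called. At stage 37/38 they were leukocytes (0.25, 0.010), heart (0.31, 5.3e-04), liver (0.21, 0.039), cell cycle (-0.17, 1.4e-08), neurons (-0.10, 0.012), eye (-0.26, 0.0015) and epidermis (0.13, 0.0015). At stage 41 they were heart (0.15, 0.039; 0.068 with the block, range over the alternatives 0.068 to 0.97), liver (0.21, 0.016), BMP targets (0.12, 0.027) and epidermis (0.19, 1.1e-04).

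The MO1 response grew between stages 35/36 and 41 for few genes. The endothelial lipase gene lipg.S changed by 1.59 ± 0.25 more at stage 41 (adjusted p = 0.010), in 3 of 3 replicate numbers; rasl11b.S did not pass (0.87 ± 0.17, 0.11; 0.0018 with the block, range over the alternatives 0.0018 to 0.43). In all 2 genes were called with MO1, against 165 with the block and 14 with DESeq2. The count was 1 without MO1 stage 35/36 replicate 3, MO1 stage 41 replicate 2, cMO stage 35/36 replicate 3 or cMO stage 41 replicate 3, 5 without MO1 stage 35/36 replicate 2 or cMO stage 41 replicate 2, and 6 without MO1 stage 41 replicate 1. With MO2 edgeR called 0 genes (1088 at unadjusted p under 0.05, DESeq2 2), with eif4g3.S (0.75) and mycn.L (0.72) among the closest at adjusted p = 0.36 each; the count was 1 without the library labelled ERFE MO2 stage 35/36 replicate 1 or MO2 stage 41 replicate 1. Hypoxia genes changed more at stage 41 with MO1 (median 0.12, adjusted p = 3.4e-04; 0.013 with an estimated correlation).

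Remaining stage differences of lists rest on the preset correlation, with adjusted p of 0.22 or more with an estimated one. With MO1 they were exocrine pancreas (-1.09, adjusted p = 6.1e-06), the gut list (-0.31, 1.5e-05), cell cycle (-0.10, 5.3e-05), skeletal muscle (-0.08, 0.022), BMP targets (0.18, 0.0053), the stress list (0.15, 3.3e-04), neurons (0.18, 1.5e-05) and interferon genes (0.11, 0.047; 0.052 with the block, range over the alternatives 0.052 to 0.84). Liver differed only with the block (0.11, 0.091; 0.048 with it, range 0.048 to 0.89). With MO2 they were the erythroid list (-0.16, 0.0064), exocrine pancreas (-1.20, 7.4e-05), the gut list (-0.35, 2.0e-05), eye (-0.42, 0.0049) and BMP targets (0.18, 2.0e-04). Without the library labelled ERFE MO2 stage 35/36 replicate 1 the MO2 eye difference had the opposite sign (0.27, 0.0044), and the other 4 lists were called with the same sign.

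Normal development between stages 35/36 and 41 changed many genes in uninjected embryos. The elastase gene cela1.S rose by 9.29 ± 1.43 log2 units (adjusted p = 4.8e-06) and cldn18.S, a stomach and lung tight junction gene, by 8.72 ± 1.08 (2.1e-07), while the cartilage matrilin gene matn1.L had 1775 counts against 1 (ratio 1688, 95% counting interval 303 to 66694; 17.7 ± 12.0 CPM at stage 41). The hyaluronan synthase gene has1.S fell by 6.04 ± 0.91 (3.7e-06), the synaptotagmin gene syt13.S by 5.48 ± 1.44 (0.0025), and msgn1.L, a regulator of presomitic mesoderm, had 3 counts against 92 (32.3-fold lower, interval 10.7 to 159). These held in 3 of 3 replicate numbers, and 13727 genes changed in total (6807 higher, 6920 lower).

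A score of developmental stage was built on 5051 of these genes, with the uninjected means set to 0 at stage 35/36 and 1 at stage 41, so injected groups are compared with each other and not with uninjected embryos. At stage 41 it was 1.0 ± 0.157 in uninjected embryos, 0.918 ± 0.186 with 10 ng cMO, 0.830 ± 0.143 with MO1, 0.921 ± 0.204 with 20 ng cMO and 0.777 ± 0.145 with MO2. The means at stage 37/38 were 0.252 ± 0.0627, 0.283 ± 0.0626, 0.236 ± 0.0420, 0.244 ± 0.0652 and 0.208 ± 0.0492 in the same order, and at stage 35/36 they were 0 ± 0.0534, 0.0310 ± 0.0126, 0.0312 ± 0.0713, 0.0416 ± 0.0328 and 0.0893 ± 0.169. Averaged over stages the difference from cMO was -0.0449 with MO1 (permutation p = 0.35; 0.070 with replicate number as a block, range over the alternatives 0.065 to 0.69) and -0.0443 with MO2 (permutation p = 0.47), and neither passed. At stage 41 alone the differences were -0.0876 with MO1 and -0.145 with MO2, each lower in 3 of 3 replicate numbers; a single stage was not tested. Without the library labelled ERFE MO2 stage 35/36 replicate 1, which scored 0.282, the MO2 difference was -0.0753 (permutation p = 0.16). With replicate number as a block as well it was -0.0726, lower in 7 of 8 pairs, and passed (permutation p = 0.016, range over the alternatives 0.016 to 0.90).

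**Figure D4:**
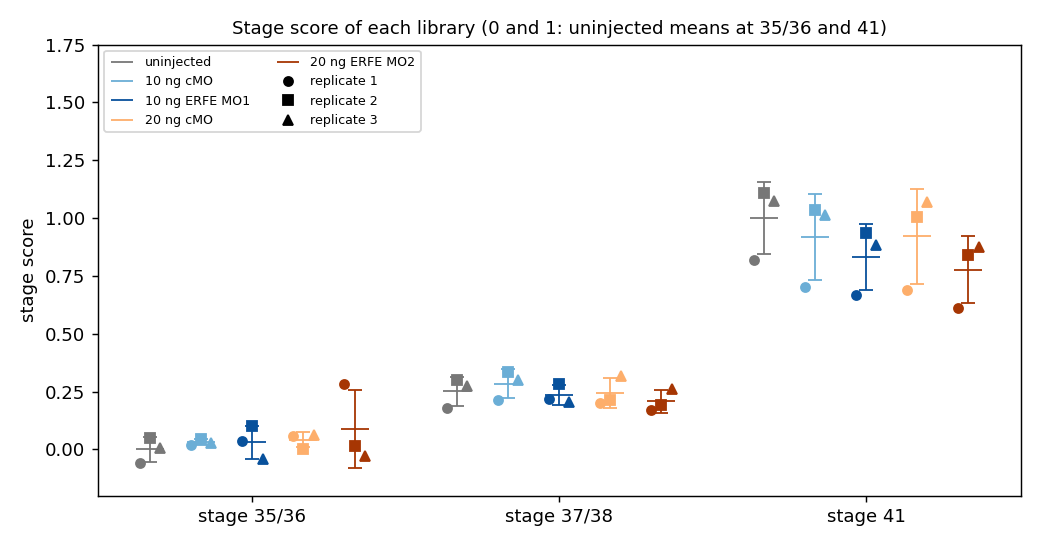
Stage score (vertical axis, no unit; 0 and 1 are the uninjected means at stages 35/36 and 41) of each library, by stage and condition; points are libraries shaped by replicate number, bars are means with standard deviation. The library labelled ERFE MO2 stage 35/36 replicate 1 lies at 0.282, among the stage 37/38 libraries, whose scores run from 0.169 to 0.335.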

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

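The tests on the library labelled ERFE MO2 stage 35/36 replicate 1 and on ghrh and rpn2 were chosen after the results were seen; the tests of slower development and of other splits of the samples were planned before, apart from the late rate of change and the replicate numbers left out of the observed change in the former, and the number and reading of the drawn splits in the latter.

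The response to MO1 differed from that to MO2 in 13 genes at stage 37/38, and the p53 list differed at each stage (median differences 0.13, 0.44 and 0.21), as did the cell cycle list at stage 41 (-0.29). The first p53 difference was 0.40 without MO2 stage 35/36 replicate 1. With fry, which also allows for correlation, the p53 difference had adjusted p = 0.086, 1.3e-04 and 0.058 and the cell cycle difference 0.058. The MO1 response also differed between stages 41 and 35/36 in 2 genes and in the hypoxia list (median 0.12). MO1 and MO2 differ in sequence and dose (10 and 20 ng), which the design cannot part. Whether the p53 rise and cell cycle fall with MO1 reflect ERFE loss or the oligo itself was not tested.

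The library labelled ERFE MO2 stage 35/36 replicate 1 is close to a library of another group, MO1 stage 37/38 replicate 2. The chi-square per gene of the next closest pair of all libraries is 3.23 times that of this pair, and the stage score of the library (0.282) lies among those of stage 37/38 (0.169 to 0.335) and above the other libraries of stage 35/36 (up to 0.0994), which is consistent with a mislabelled sample. Only 1.57% of 29971 genes have equal counts, which argues against the same counts under both names. The MO1 library scores 0.284 and correlates with its own replicate number (0.527), while the MO2 library does not (0.0777). A wrong label may thus be that of the MO2 library. Whether RNA or library is shared stays open, and mixed RNA was not tested. The p53 and endothelial calls for MO2 at stage 35/36 that hold with an estimated correlation (adjusted p = 0.0083 and 0.0078) are lost without it (0.28 and 0.061).

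The genes ghrh.L, ghrh.S and rpn2.S differ between ERFE morpholinos and control morpholino, in the direction opposite to that between control morpholino and uninjected embryos; rpn2.L did not pass against control morpholino. Of 14 changes called against control morpholino at stages with counts in uninjected embryos 0 passed against those. In 0 of 14 was at least 50% of the change also seen against uninjected embryos. These genes, repeated over stages, were chosen after opposite changes were seen, which favours both results, so neither tests ERFE knockdown. Both an effect of the control morpholino and a rise after injection that ERFE knockdown prevents stay open. Against uninjected embryos ghrh.S was 2.65 and 2.41 (log2) with MO2 at stages 37/38 and 41 (adjusted p = 0.17 and 0.073) and 0.14 and -0.64 with MO1 (1.0 and 0.89), so a smaller effect of injection stays open. It has 0 counts in uninjected embryos at stage 35/36, so no such value is given there.

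The exocrine pancreas, gut and liver lists were lower at stage 41 with the preset correlation alone (adjusted p of 0.13 to 0.46 with an estimated one). Slower development would lower them too. Given the stage scores (differences of -0.0623 with MO1 and -0.129 with MO2, on 4642 genes), slower development would account for 16.1%, 18.1% and 10.6% of the MO1 medians of exocrine pancreas, gut and liver, and for 8.88% of the MO2 median of liver, too little to be the whole cause. With MO2 it would account for 45.2% of the gut median (36.7% to 57.0% with 1 replicate number left out) and 39.4% of the exocrine pancreas median (32.0% to 49.65%, under the limit of 50%). The latter meets the planned criterion, but these values assume an even change between stages 35/36 and 41. At the rate from stage 37/38 to 41 the exocrine pancreas share is 52.3% with MO2 and 21.3% with MO1. Slower development and, untested, an organ defect or a tissue change specific to ERFE stay open.

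Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. The real and the highest other count were 124 and 0, 191 and 0, and 479 and 3134 with MO1, and 6 and 157, 31 and 0, and 131 and 0 with MO2. The control morpholino gave 2 and 0, 2 and 0, and 2 and 1 with 10 ng and 5 and 0, 4 and 0, and 4 and 1 with 20 ng, and the uninjected stages 13727 and 0. The 3134 genes come from the split of cMO replicates 1 and 3 with MO1 replicate 1 against the rest, and the 157 from the same split of the MO2 libraries, so 1 other split was as large in each (2 of 10), and only the real 1 elsewhere. The 3134 genes point to a structure of the samples by replicate number; with replicate number as a block the MO1 count at stage 41 is 4256. The libraries behind the 157 genes include the one labelled ERFE MO2 stage 35/36 replicate 1, so the source of these stays open. The 3 other splits that part all 3 replicate pairs, as the real split does, called 0 genes in each ERFE comparison.

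For gene lists the real and highest other counts were 6 and 11, 9 and 13, and 15 and 13 with MO1, and 5 and 12, 13 and 12, and 14 and 11 with MO2; of 10 splits 6, 4 and 1, and 9, 1 and 1 were as large. For MO1 at stages 35/36 and 37/38 and MO2 at stage 35/36, list counts as large as the real ones thus also arise from other splits. Splits that part all replicate pairs gave at most 5, 8 and 9 lists with MO1 and 12, 10 and 10 with MO2. With an estimated correlation 2, 2 and 5 and 2, 1 and 0 of the real calls hold.

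For genes changed with both morpholinos the real counts were 2, 4 and 52 and the highest other of 100 drawn splits (of 200) 0, 0 and 5, with only the real 1 as large. Of the 99 others 6, 1 and 7 called any gene with each morpholino, and without such calls the shared count is 0, so these splits do not test chance. Nor do those for the differences between MO1 and MO2 and between stages. A split can leave the libraries of 1 morpholino or stage parted as labelled, and then carries its treatment effect, and with a real count of 0 every split is as large. The real counts for MO1 against MO2 were 0, 13 and 0 and the highest other 242, 226 and 6357, with 80, 10 and 80 of 80 drawn splits as large; at stage 37/38 all 9 others as large were parted as labelled in this way. Between stages 41 and 35/36 the real counts were 2 and 0 and the highest other 868 and 265, with 14 and 80 of 80 as large, and 11 of the 13 others with MO1 were parted as labelled. The 6357 genes come from a split that sets cMO replicates 1 and 3 and MO1 replicate 1 apart, as in the split behind the 3134 genes. Their source stays open as well.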

How the results depend on the processing

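The alternatives with 44 libraries (without the library labelled ERFE MO2 stage 35/36 replicate 1), with 44 libraries and the replicate block, and with uninjected embryos as control were chosen after the results were seen; all others were planned. Counts below are of genes in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named, in the order of stages 35/36, 37/38 and 41, and most counts that moved by no more than 1.5 times are left out.

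Scaling by RLE moved no count by more than 1.5 times and reversed 0 of 300 named gene results (3 gained and 3 lost a call). Without the gene filter the MO2 count at stage 37/38 was 14 in place of 31, and 14 named gene results lost their call. A fit to the stages compared alone reversed 0 of 300 named gene results, 11 gained and 69 lost a call.

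With DESeq2 the counts were 228, 350 and 756 with MO1, 45, 79 and 309 with MO2, and 13, 8 and 125 with both. At stage 41 they were 4 with 10 ng and 12 with 20 ng of control morpholino. The difference between MO1 and MO2 had 29 genes at stage 37/38 and 1 at stage 41, and that between stages 41 and 35/36 had 14 with MO1 and 2 with MO2. DESeq2 reversed 0 named gene results; 40 gained a call.

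When the stages compared were fitted alone, the counts were 45, 301 and 113 with MO1, 2, 54 and 25 with MO2, and 1 and 7 with both at stages 35/36 and 41. The control morpholino gave 0 genes with 10 ng at stage 41, and 2 and 0 with 20 ng at stages 35/36 and 41. The difference between MO1 and MO2 at stage 41 had 3 genes and the MO1 difference between stages 41 and 35/36 had 0. Fewer libraries then carry the estimate of spread.

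With the lane term the counts were 296, 417 and 1566 with MO1, 23, 94 and 700 with MO2, and 6, 20 and 311 with both. The control morpholino gave 4 and 4 with 10 ng at stages 35/36 and 41, and 15, 9 and 8 with 20 ng. The difference between MO1 and MO2 at stage 41 had 4 genes, and that between stages 41 and 35/36 had 29 with MO1 and 1 with MO2. Of 300 named gene results 52 gained a call, 1 lost it and 0 reversed.

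With the replicate block the counts were 795, 1158 and 4256 with MO1, 179, 514 and 1846 with MO2, and 43, 87 and 821 with both. The control morpholino gave 5, 4 and 15 with 10 ng and 22, 13 and 21 with 20 ng. The difference between MO1 and MO2 had 3, 141 and 92 genes, and that between stages 41 and 35/36 had 165 with MO1 and 53 with MO2. All 124, 191, 479, 6, 31 and 131 genes called without the block in the ERFE comparisons were called with it. For MO2 at stage 35/36 the block also called the leukocyte list (adjusted p = 0.022, range over the alternatives 2.4e-04 to 0.99) and the pronephros list (0.048, range 0.0041 to 0.49), and for the MO2 difference between stages skeletal muscle (0.045, range 0.015 to 0.85). Among named genes 92 of 300 results gained a call and 0 lost it or reversed. Beyond these and the values above the block changed no other list call, and it gave 6.92% false calls in simulated data.

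With 44 libraries 20 genes changed with MO2 at stage 35/36, 1 with both at that stage, and the difference between MO1 and MO2 had 3, 24 and 2 genes; the MO2 difference between stages 41 and 35/36 had 1. The MO1 counts were 160, 258 and 530, the other MO2 counts 46 and 192, and 5 and 72 genes changed with both at stages 37/38 and 41. The neuron gene stx1a.S with MO2 at stage 35/36 reversed to -0.012.

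With 44 libraries and the replicate block the counts were 1081, 1519 and 5121 with MO1, 368, 844 and 2363 with MO2, and 76, 168 and 1064 with both. The control morpholino gave 5, 6 and 17 with 10 ng and 23, 22 and 23 with 20 ng. The difference between MO1 and MO2 had 116, 249 and 402 genes, and that between stages 41 and 35/36 had 296 with MO1 and 71 with MO2.

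With the uninjected control the count was 299 with MO1 at stage 37/38, and 0, 20 and 234 with MO2; the MO2 list count at stage 35/36 was 9 in place of 5. Named genes with reversed sign were ghrh.L (0.079, 0.46 and 0.88 with MO1, 0.65, 0.76 and 1.41 with MO2), ghrh.S (0.14 with MO1 at stage 37/38), rpn2.S (-0.14 and -0.20 with MO2 at stages 35/36 and 37/38) and fam132b.L (-0.20 with MO1 at stage 35/36). Of the values of ghrh and rpn2 not named by rule, several not called against control morpholino, these reversed too: ghrh.S (2.65 and 2.41 with MO2 at stages 37/38 and 41), rpn2.S (-0.098 and -0.052 with MO1 at stages 35/36 and 41, -0.077 with MO2 at stage 41) and rpn2.L (-0.30, -0.15 and -0.20 with MO1, -0.21, -0.35 and -0.32 with MO2). At stage 35/36 ghrh.S, at 0 counts in uninjected embryos, was higher than these with both morpholinos. With MO2 the neuron and endocrine genes stx1a.S (-0.057 at stage 35/36), cck.L (-0.14 at stage 37/38), syn2.S (-0.10 at stage 37/38) and elavl4.L (-0.00693 at stage 41) reversed as well; none of these had passed.

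For gene lists camera with an estimated correlation and fry each called 2, 2 and 5 lists with MO1 and 2, 1 and 0 with MO2.

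Leaving out 1 library gave 34 (MO1 replicate 1) to 182 (MO1 replicate 2), 61 (MO1 replicate 1) to 198 (MO1 replicate 2) and 108 (cMO replicate 3) to 498 (MO1 replicate 1) genes with MO1. The MO2 counts were 1 (cMO replicate 1) to 20 (MO2 replicate 1), 6 (cMO replicate 1) to 24 (MO2 replicate 3) and 13 (MO2 replicate 2) to 200 (cMO replicate 1). With both morpholinos they were 1 (20 ng cMO replicate 1) to 2, 1 (20 ng cMO replicate 1) to 4, and 4 (MO2 replicate 2) to 77 (10 ng cMO replicate 1). For 10 ng of control morpholino the stage 41 count was 1 (uninjected replicate 1) to 2. For 20 ng the counts were 2 (cMO replicate 1) to 5, 2 (cMO replicate 1) to 4 and 2 (uninjected replicate 1) to 4.

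Differences between MO1 and MO2 had 0 to 3 (MO2 replicate 1), 0 to 38 (MO1 replicate 2) and 0 to 1 (MO2 replicate 3) genes when 1 library was left out. Differences between stages 41 and 35/36 had 1 (MO1 stage 41 replicate 2) to 6 (MO1 stage 41 replicate 1) genes with MO1 and 0 to 1 (MO2 stage 35/36 replicate 1) with MO2. List counts were 7 (MO1 replicate 1) to 15 (cMO replicate 1) with MO1 at stage 41 and 4 (cMO replicate 2) to 8 (cMO replicate 1) with MO2 at stage 35/36.

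The sign of fam132b.L depended on single libraries where its change was small. Leaving out 1 library its log2 fold change was -0.33 to 0.45 with MO1 and -0.35 to 0.16 with MO2 at stage 35/36 (highest without replicate 3 of the control morpholino, lowest without replicate 3 of the ERFE morpholino). For 10 ng of control morpholino it was -0.66 to 0.033, -0.077 to 0.20 and -0.29 to 0.21, and for 20 ng -0.31 to 0.10 at stage 37/38 and -0.35 to 0.12 at stage 41. With MO2 at stage 35/36 stx1a.S was -0.012 to 0.87, lowest without the library labelled ERFE MO2 stage 35/36 replicate 1. Over all leave-out fits of named genes 1479 results were on the same side of the threshold, 18 gained and 382 lost a call, and 17 reversed.

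The stage score differences were tested by permutation. They were -0.0358 (permutation p = 0.43) with MO1 and -0.0367 (0.55) with MO2 on an axis without genes called in an ERFE comparison. On an axis with absolute log2 fold change over 2 they were -0.0657 (permutation p = 0.19) and -0.0586 (0.36), and with RLE -0.0454 (0.34) and -0.0441 (0.47). With the replicate block the permutation p was 0.070 and 0.29 (512 relabelings), and without replicates 1, 2 or 3 it was 0.065, 0.41 and 0.69 with MO1 and 0.056, 0.68 and 0.90 with MO2. With 44 libraries the MO2 difference was -0.0753 (permutation p = 0.16). With 44 libraries and the replicate block it was -0.0726 over the 8 remaining pairs, 7 of them lower (permutation p = 0.016, 256 relabelings, range over the alternatives 0.016 to 0.90), the only alternative of these in which a difference passed.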

Other observations

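The sterol synthesis list was written and tested after sqle.L and hmgcs1.L had been seen among the genes changed with both morpholinos; nothing in this part was planned.

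A candidate explanation for part of the shared response at stage 41 is a coordinated rise of sterol synthesis. Of 31 genes of the pathway 30 were above 0 with MO1 and 31 with MO2 (median log2 fold change 0.82 and 0.70), with p = 4.5e-04 and p = 4.4e-04 in camera with an estimated correlation; 18 and 7 rose over all genes. At stages 35/36 and 37/38 the camera p-values with an estimated correlation were 0.53 and 0.18 with MO1 and 0.45 and 0.60 with MO2. With replicate number as a block MO1 passed at stage 37/38 (p = 0.031 in camera with an estimated correlation, range over the alternatives 3.6e-06 to 0.18), with 5 genes higher. Without the block the difference between stages 41 and 35/36 had p = 0.0010 and 0.0039 with an estimated correlation. MO1 and MO2 did not differ at stage 41 at this precision in camera with an estimated correlation (p = 0.49). Such genes are induced when cells hold little sterol, so lower yolk lipid use or lower lipid uptake might produce the same rise; none of these was tested. Because the genes that raised the idea are on the list, it is a hypothesis to test on other embryos.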
